A study of Mus musculus with 17 samples.

How the data were processed

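RNA enriched for the ribosome-bound RNA of POMC neurons was sequenced from the mediobasal hypothalamus of 17 mouse samples. POMC (pro-opiomelanocortin) neurons are appetite-suppressing neurons of the arcuate nucleus. In RiboTag mice an HA-tagged ribosomal protein is made in cells where the chosen driver gene is or has been active. Pulling down the tag with an antibody enriches the RNA those cells are translating. Per the labels' protocols, dams ate standard chow or a 45% high-fat diet (HFD) from 6 weeks of age, were mated after 4 weeks on the diet and stayed on it until postnatal day 21. Samples were taken from the offspring at postnatal day 0 (P0) and day 21 (P21, weaning), with 5 chow and 5 HFD samples at P0 and 3 chow and 4 HFD samples at P21. The labels call the samples biological replicates and do not say which animals, litters or pools each came from, so the p-values measure the spread between these samples. The labels give no library batch and no sex.

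Per the labels' protocols, libraries were made with the Nextera XT kit and sequenced on a HiSeq instrument as single reads of 50 bases. Per the submitters' processing notes, the tools were FastQC, TopHat2 2.0.13, Picard 1.80, HTSeq 0.6.1 and edgeR, with genome build mm10. The settings and the choice of genes kept are not given in the sources used here. The strand setting of the gene counting is likewise not given in the sources used here.

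The deposited table holds normalized signal, in scaled CPM-like units with 2 decimals, and not raw counts. From the values, each column is a set of whole-read counts divided by an effective library size. The column sums run from 0.908 to 1.105 M (M, mega), and the scaling factors of the 17 columns have a geometric mean of 1.00. In every library at least 99.98% of the non-zero values lie at a whole number of reads within the rounding of the table, against 22.2% to 37.0% for values placed at random. The value of 1 read gave the depth of each library in reads counted to the genes of the table, 22.4 to 37.1 M. A single read was worth 0.0275 to 0.0460 units, and the limit of 3 reads that a value of 0 allows ranged from 0.0826 to 0.138 units between libraries. That limit covers counting error only. In 6 libraries the steps of 1 read were sharp enough to recover the counts, and in the other 11 the rounding blurred them.

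The table holds 15355 genes by symbol, each once. It also has 15 columns that are empty. Of the symbols, 15227 (99.2%) matched the GENCODE M21 annotation of GRCm38, the same assembly as mm10, which gave gene identifiers, coordinates and GC content. Of the 115 genes named by the rule given below, 38 share exonic bases with another annotated gene and 14 share more than 10% of theirs. Pitx1, Cga and Ttr, named outside that rule, were not examined for overlap. The largest shares are 66.2% for Rpl35 with Wdr38, 55.6% for Gpc2 with a gene model on the same strand, 54.6% for Sox4 with a non-coding RNA on the opposite strand and 33.6% for Rarres2 with Lrrc61. Nptxr shares 17.2% with Npcd on the same strand, Tmtc4 19.1%, H1fx 17.5% and Agrp 11.3%.

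Each comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(value + 1), with an intensity trend in the prior variance and the non-robust prior, and Benjamini-Hochberg adjustment at 0.05, two-sided. The fold changes are log2 differences on that scale, so they understate the change of genes near 0. A gene was tested when its value was above 1 in at least as many libraries as the smaller group holds. The comparisons were HFD against chow at P0, HFD against chow at P21, P21 against P0 in chow offspring, and the diet by age interaction over all 17 libraries. Each of the first 3 used its own libraries alone, with no covariate. An edgeR quasi-likelihood count test had been foreseen in case the values were counts. Because they were not, edgeR 4.0.16 was run only on the reads recovered in the 6 libraries named above, which gave 3 chow against 2 HFD libraries at P0 and 3 P0 against 1 P21 library in chow offspring. The lone P21 library is assumed there to vary like the others.

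Of 29 gene lists, those with at least 2 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated for each list and with fry. The lists cover POMC-neuron identity, other hypothalamic neurons, other cell types of the dissected tissue, and pathways of diet, stress and development. Members were also counted past the gene test over all genes and adjusted over the list alone. The comparisons, the gene lists, the camera test at both diet comparisons and the naming rule were chosen before the data were examined. The rule named Pomc, Cartpt, Agrp, Npy and Lepr in each comparison. It added the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, with unnamed gene models counted and not named, filled up to 10 by the smallest unadjusted p where fewer passed. It also took 3 members with the smallest p from each list worth a sentence. A few genes that the rule takes are not reported here. What made a list worth a sentence was settled after the list results were seen. In the diet comparisons it was a camera adjusted p under 0.05 or a member past the threshold over all genes, and for age the 8 lists with the smallest camera p. The gene list tests for age and for the interaction were added after the data were seen. The non-robust prior was settled after a run with it had been seen. Values singled out outside the rule are described as chosen after their values were seen.

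The alternatives tried were a median-of-ratios rescaling, an upper-quartile rescaling, no filter on low values, a pseudocount of 0.1, erythroid and sex-linked genes left out, the replicate number as a block, 1 surrogate variable from sva 3.50.0, all groups in 1 fit, and each replicate left out in turn. Added after the data were seen were the robust prior, sample weights, a filter at 5, removal of each library's GC trend by lowess with a span of 0.3, log2 Pomc as a covariate for the diet comparisons, and the count test. DESeq2, voom and an Xist covariate were not run. Voom and DESeq2 need counts in all libraries, and Xist is not among the genes of the table used here. Of the 5 sex-linked genes 4 were tested as a list. Their median log2 change in HFD offspring was 0.36 at P0 (camera adjusted p = 0.221) and 0.11 at P21 (camera adjusted p = 0.542). The balance of sexes between the diets was not tested. Sample weights on log values stood in for voom's weights, and surrogate variables were taken from log values.

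The fit was tested on simulated data with genes changed by known folds. At P0, 81.5% of genes changed 4-fold, 50.7% of those changed 2-fold and 10.4% of those changed 1.5-fold were recovered, and 8.74% of the calls were false. At P21 the shares were 75.8%, 13.4% and 1.49%, with 4.76% false. For age they were 77.3%, 22.4% and 4.48%, with 5.48% false. The interaction gave 62.1%, 17.9% and 0%, with 1.85% false. A raised list was found in each of the 4 comparisons, and camera called 1 of 26 unchanged lists at P0 and 0 of 27 in each of the others. The simulated genes were drawn independently of each other, with no factor shared within a library. The false calls therefore do not carry over to genes that vary together. In the data the estimated correlation at P21 was 0.76 for the microglia list and 0.86 for the ribosomal list.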

Results

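The 17 libraries hold RNA pulled down with POMC-neuron ribosomes, which also held markers of other cells, from offspring of chow-fed and HFD-fed dams. At P0 there were 5 libraries per diet, and at P21 there were 3 chow and 4 HFD libraries. The depth, as reads counted to genes of the table, averaged 27.2 ± 3.20 M reads (SD, n = 5) in chow P0, 26.6 ± 5.34 M reads (n = 5) in HFD P0, 31.3 ± 7.82 M reads (n = 3) in chow P21 and 31.9 ± 0.706 M reads (n = 4) in HFD P21. Values are in scaled CPM-like units, and fold changes are log2 differences of value + 1. Pomc itself, the precursor of the appetite-suppressing peptide alpha-MSH, was measured at 645 ± 481 in chow P0, 335 ± 408 in HFD P0, 6875 ± 4516 in chow P21 and 8518 ± 978 in HFD P21 (mean ± SD).

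**Figure D1:**
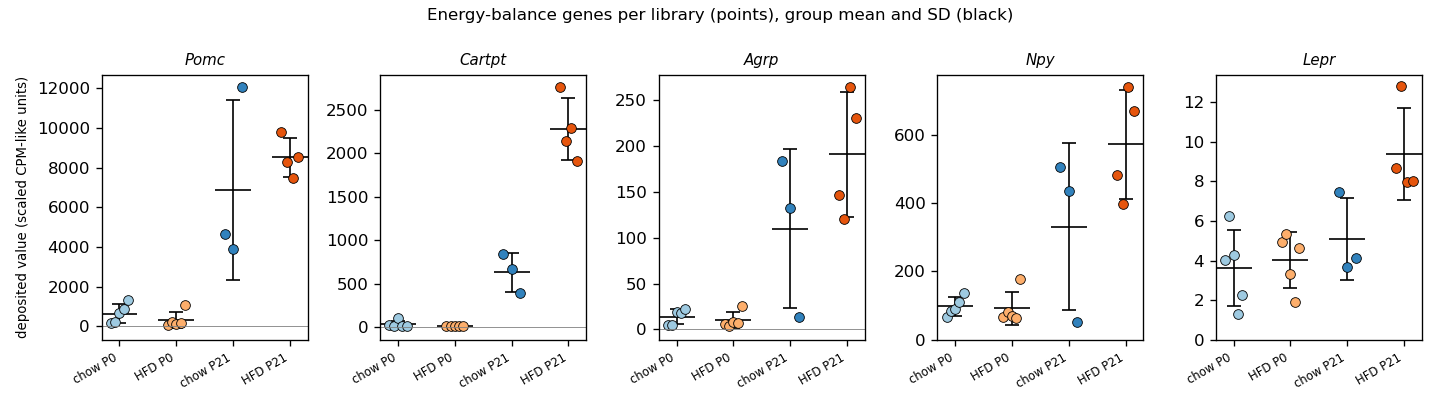
Scaled CPM-like values of Pomc, Cartpt, Agrp, Npy and Lepr in each library (points) by diet and age, with group mean and SD in black. Cartpt averaged 630 in the 3 chow and 2275 in the 4 HFD libraries at P21, and the groups did not overlap.

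The comparison of HFD with chow offspring at P0 asks how the RNA pulled down with POMC-neuron ribosomes differed with the dam's diet at birth. In HFD offspring 40 genes fell and 1 rose, out of 14086 tested. Dapk3, a serine/threonine kinase of the death-associated family, fell from 53.9 ± 15.8 to 4.15 ± 1.43 (mean ± SD, n = 5 per group), a log2 change of -3.41 (SE 0.26, adjusted p = 3.58e-05). Ano8, an anoctamin of endoplasmic reticulum contact sites, fell from 36.3 ± 16.5 to 1.85 ± 1.44 (-3.72, SE 0.35, adjusted p = 0.000221). Alyref, an mRNA export factor, fell from 104 ± 15.0 to 23.9 ± 9.33 (-2.18, SE 0.27, adjusted p = 0.00396). Col11a2, a fibrillar collagen chain, rose from 0.224 ± 0.206 to 3.31 ± 1.52 (1.77, SE 0.29, adjusted p = 0.0162).

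Nptxr, a receptor for neuronal pentraxins at synapses, fell by 2.56 on the log2 scale, from 17.3 ± 7.27 to 1.99 ± 0.842. Grin2d, an NMDA receptor subunit, fell by 2.33, Hcn2, a hyperpolarization-activated cation channel, by 2.19, and Kcnk12, a potassium channel, fell by 2.24. Gpr27, an orphan receptor, fell by 2.19, H1fx, a linker histone, fell by 2.15, and Fam105b, a deubiquitinase, fell by 2.09. Syn2, a synaptic vesicle phosphoprotein, fell from 246 ± 61.4 to 91.5 ± 19.4, which is -1.41 (SE 0.19, adjusted p = 0.00828). Dapk3 lies on chromosome 10 from 81183005 to 81193197 (mm10). No other gene rose. The next by p were Plaa at 0.68, Zc3h3 at 0.95, Fam135a at 0.88, Uhrf1bp1l at 0.68, Dclre1a at 1.25, Tro at 0.72, Kdm3a at 0.94, Srrm1 at 1.03 and Sh3bgr at 1.19, which did not pass (adjusted p from 0.0543 to 0.0988). Without HFD replicate 5 Plaa (0.69), Zc3h3 (1.09), Fam135a (0.97), Uhrf1bp1l (0.72), Tro (0.72) and Srrm1 (1.12) passed, as did Tro without HFD replicate 2 (0.82) and Srrm1 without chow replicate 2 (1.23).

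**Figure D2:**
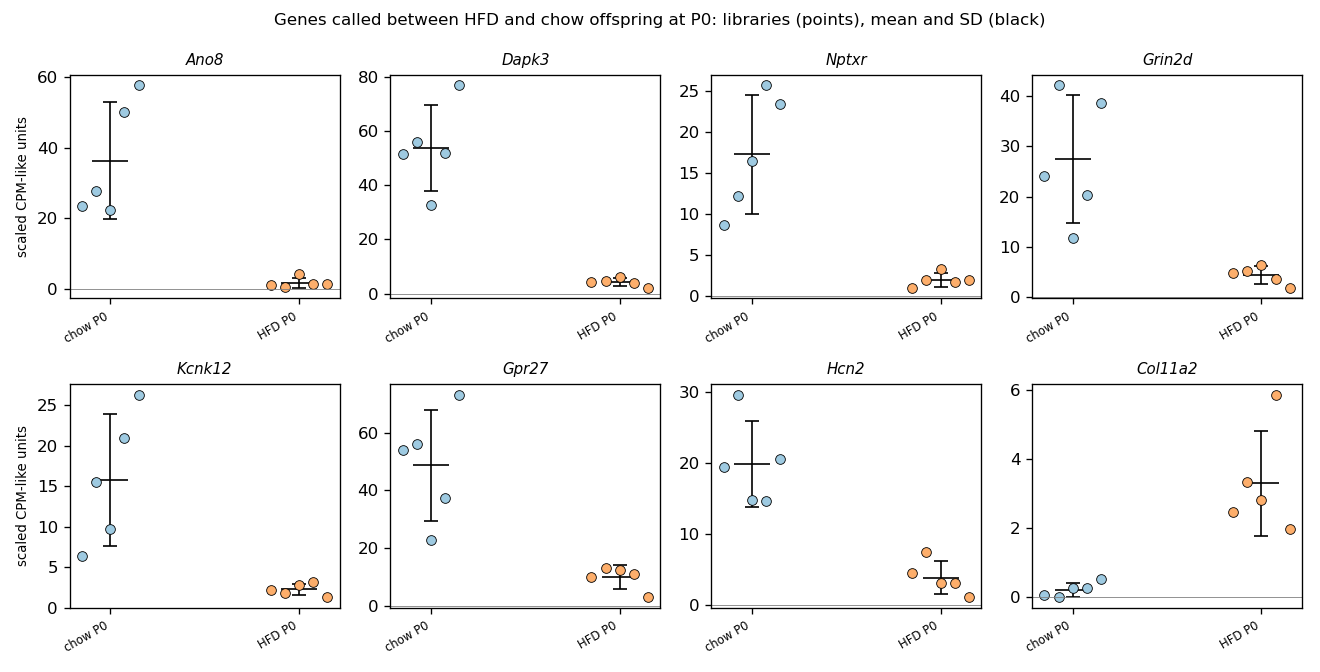
Scaled CPM-like values at P0 of 7 genes that fell and of Col11a2, which rose, in each library (points) by diet, with mean and SD in black. Dapk3 averaged 53.9 in the 5 chow and 4.15 in the 5 HFD libraries, with no overlap between them.

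The appetite genes did not pass at P0. Pomc was at -1.16 (SE 0.66, adjusted p = 0.621), Cartpt, which encodes the CART peptide of POMC neurons, at -0.53 (adjusted p = 0.819), and Agrp, the peptide of the opposing hunger neurons, at -0.42 (adjusted p = 0.839). Npy, made by the same hunger neurons, was at -0.17 (adjusted p = 0.892), and Lepr, the leptin receptor, at 0.17 (adjusted p = 0.915). HFD replicate 5 stood apart, with Pomc at 1057 against 90.7 to 246 in the other HFD libraries, and so did chow replicate 3, with Cartpt at 106 against 7.21 to 22.1 in the other chow libraries. With 1 library left out Agrp ran from -0.79 (HFD replicate 5) to -0.20 (HFD replicate 2) and Npy from -0.44 (HFD replicate 5) to -0.04 (chow replicate 5). Cartpt ran from -0.85 (chow replicate 4) to 0.07 (chow replicate 3) and Lepr from -0.05 (chow replicate 4) to 0.36 (chow replicate 2). Of the 36 glutamatergic synapse genes 1 fell, Grin2d, and adjusted over the list alone it was again 1. Prkcb, a protein kinase C, was at -0.40 (-0.22 without HFD replicate 5) and did not pass. Of the 26 presynaptic genes 1 fell, Syn2, also 1 adjusted over the list alone. Vamp1, a vesicle fusion protein, was at 0.69 and Rims1, an active-zone protein, at -0.55. Camera called 0 of 27 lists, with 3 at an unadjusted p under 0.05, and fry called 0. The lowest camera adjusted p was 0.112, for nuclear oxidative phosphorylation (median -0.08, 46 of 52 members below 0), and it was 0.928 with an estimated correlation. With 1 library left out camera gave 0 to 5 lists. Nuclear oxidative phosphorylation passed without chow replicate 2, chow replicate 3, HFD replicate 2 or HFD replicate 3, with a median from -0.13 (chow replicate 3) to -0.05 (HFD replicate 5). The ribosomal list passed without chow replicate 1, chow replicate 2 or HFD replicate 5, with a median from -0.07 (HFD replicate 2) to 0.24 (HFD replicate 5) and adjusted p from 1.15e-07 to 0.977. Fibroblast genes passed without chow replicate 2 (0.53) or HFD replicate 1, and cholesterol synthesis genes without chow replicate 2 or HFD replicate 5 (-0.35). Without HFD replicate 5 the POMC identity (-0.32), presynaptic (-0.19) and hypoxia (-0.24) lists also passed.

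The P0 test called 41 genes with limma, and 1307 had an unadjusted p under 0.05. In all 41 the groups did not overlap, as in 345 of all 14086 tested genes (2.45%), where chance gives 0.794%. The 40 genes that fell also differed between P21 libraries of the same diet, with a median SD of 0.98 there on the log2 scale against 0.31 for all genes. Dapk3 ran from 7.86 to 68.5 in chow and from 2.17 to 84.3 in HFD libraries at P21. Leaving out 1 library gave 23 genes without chow replicate 2, 24 without chow replicate 4, 18 without chow replicate 5, 21 without HFD replicate 1, 24 without HFD replicate 4 and 135 without HFD replicate 5, and 18 genes were called in every such fit, Dapk3, Ano8, Alyref, Nptxr, Grin2d, Hcn2, Kcnk12, Syn2 and Col11a2 among them. On the 5 libraries with recovered reads edgeR called 3 genes, all lower in HFD and all among the 40, and limma called 24.

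The comparison at P21 asks the same at weaning. In HFD offspring 14 genes rose and 11 fell, out of 14070 tested. Cartpt rose from 630 ± 223 (mean ± SD, n = 3) to 2275 ± 359 (n = 4), a log2 change of 1.91 (SE 0.23, adjusted p = 0.0137). Its gene lies on chromosome 13 from 99898489 to 99901091 (mm10). Npy1r, a receptor for neuropeptide Y, rose from 72.8 ± 14.1 to 192 ± 11.4 (1.41, SE 0.16, adjusted p = 0.0137). Asb4, a ubiquitin ligase adaptor of arcuate neurons, rose from 189 ± 64.5 to 606 ± 57.5 (1.73, SE 0.21, adjusted p = 0.0137). Apoe, a lipid carrier made mainly by astrocytes, fell from 3001 ± 532 to 1354 ± 310 (-1.16, SE 0.19, adjusted p = 0.0412).

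Among the other rises, Timp1, an inhibitor of matrix metalloproteases, went from 1.55 ± 0.591 to 11.6 ± 3.57 (2.29) and Serpina3n, a serine protease inhibitor, from 123 ± 45.6 to 344 ± 61.9 (1.54). Tmtc4, an enzyme of the endoplasmic reticulum, rose by 1.62, Tnfrsf11b, which encodes osteoprotegerin, by 1.59, and Cited1, a transcriptional co-regulator, by 1.56. Gch1, the rate-limiting enzyme of tetrahydrobiopterin synthesis, and Rrad, a small GTPase, each rose by 1.36. Among the falls, Hepacam, an adhesion protein of astrocytes, went from 104 ± 29.8 to 39.0 ± 5.95 (-1.36), Gjb6, an astrocyte connexin, was at -1.31, and Agt, angiotensinogen, went from 447 ± 23.8 to 206 ± 52.4 (-1.15). Clic5, a chloride intracellular channel protein, went from 5.83 ± 0.787 to 0.533 ± 0.169 (-2.16). Lhfp fell by 1.38, Carhsp1 fell by 1.17, Mpzl1 fell by 1.09, Ttyh1 fell by 1.04 and Deaf1 fell by 0.98.

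Pomc did not pass at P21 (0.49, SE 0.31, adjusted p = 0.447), nor did Agrp (1.35, adjusted p = 0.329), Npy (1.29, adjusted p = 0.305) or Lepr (0.79, adjusted p = 0.229). Chow replicate 3 stood apart in these genes, with Pomc at 12070, Cartpt at 391, Agrp at 14.0 and Npy at 51.9. Without it Pomc passed with a log2 change of 0.99, Agrp was at 0.22 and Npy at 0.24, and Cartpt remained past the threshold at 1.60. Without chow replicate 1 Pomc was at 0.31 and Agrp at 2.03, and without chow replicate 2 Pomc was at 0.17. Of the 20 genes of POMC-neuron identity and peptide processing, 1 rose over all genes, Cartpt, while adjusted over the list alone 5 rose and 1 fell. Chgb, a secretory granule protein, was at 0.53 and Pcsk1, the protease that first cleaves the Pomc precursor, at 0.95. The list as a whole was higher in HFD offspring (median 0.47, camera adjusted p = 0.00045), and its adjusted p = 0.473 with an estimated correlation. Its median was 0.23 without chow replicate 3, where it remained past the threshold.

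The 23 genes of the unfolded protein response were higher by camera (median 0.27, adjusted p = 0.000297), with adjusted p = 0.473 with an estimated correlation. Markers of oligodendrocytes (median -1.09) and microglia (-0.87) were lower in the same comparison. None of the unfolded protein response genes passed over all genes, and adjusted over the list alone 10 rose and 1 fell. The members of that list with the smallest p were Pdia6, a disulfide isomerase, at 0.71, Hspa5, the chaperone BiP, at 0.68, and Hsp90b1, an endoplasmic reticulum chaperone, at 0.65. The hypoxia and glycolysis list (26 genes, median 0.14) and the ribosomal protein list (76 genes, median 0.09) each had a camera adjusted p of 0.0365. With an estimated correlation the adjusted p = 0.669 for the first and adjusted p = 0.832 for the second. In the 7 fits with a library left out the hypoxia list passed in 4, lost without chow replicate 1, HFD replicate 2 or HFD replicate 3. The ribosomal list passed in 3, lost without chow replicate 2, chow replicate 3, HFD replicate 1 or HFD replicate 3, with a median from -0.02 without HFD replicate 3 to 0.20 without HFD replicate 4. Ldha, lactate dehydrogenase, was at 0.70, P4ha1, a collagen prolyl hydroxylase, at 0.99 and Pfkp, a phosphofructokinase, at 0.43, and adjusted over the list alone 3 of that list rose. Among the ribosomal proteins Rps15a was at 0.28 (0.17 without HFD replicate 1), Rps6 at 0.22 and Rpl23 at 0.24 (0.11 and 0.10 without HFD replicate 3), and none passed either way. Among 18 immediate early genes 1 rose over all genes, Junb, a Jun-family transcription factor (1.14, SE 0.19, adjusted p = 0.0412), and adjusted over the list alone 3 rose and 2 fell. Fos, the activity marker, was at 1.95 and Ier5 at -0.91, and camera did not call the list (median 0.36, adjusted p = 0.131). Without chow replicate 3 Fos passed at 2.47 and the list passed at a median of 0.43. Over the 7 fits with a library left out the median of the list ran from 0.21 to 0.43, and the list passed in 1.

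Camera called 6 lists of glial, vascular, meningeal and ventricular markers lower in HFD offspring at P21. The 14 oligodendrocyte genes had a median of -1.09 (camera adjusted p = 5.16e-11, and adjusted p = 0.473 with an estimated correlation), with 13 lower adjusted over the list alone, among them Mbp, myelin basic protein, at -1.35, Mag, a myelin adhesion protein, at -1.47 and Gpr17, a receptor of their precursors, at -1.01. The 14 microglia genes had a median of -0.87 (camera adjusted p = 3.89e-08, and adjusted p = 0.473 with an estimated correlation), 11 lower adjusted over the list alone, with C1qc, a complement chain, at -1.01, Csf1r, the receptor they need for survival, at -0.89 and Tyrobp, a signalling adaptor, at -1.12. The 18 endothelial and mural genes had a median of -0.68 (camera adjusted p = 8.56e-05, and adjusted p = 0.473 with an estimated correlation), 8 lower adjusted over the list alone, with Slco1a4, a transporter, at -1.36, Esam, an adhesion protein, at -0.98 and Cldn5, a tight junction protein, at -1.04. The 19 astrocyte, radial glia and tanycyte genes had a median of -0.66 (camera adjusted p = 7.09e-05, and adjusted p = 0.473 with an estimated correlation), 9 lower and 1 higher adjusted over the list alone, with Slc1a3, a glutamate transporter, at -0.78, Hes5, a Notch target, at -1.21 and Gja1, a connexin, at -0.96. None of these genes passed over all genes. Without chow replicate 3 the 4 medians were -0.78, -0.56, -0.46 and -0.42, all past the threshold, and without chow replicate 1 Mbp (-1.61), Mag (-1.83), Gpr17 (-1.25) and Gja1 (-1.21) passed over all genes.

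The 13 fibroblast and meningeal genes had a median of -0.61 (camera adjusted p = 0.00194), with adjusted p = 0.551 with an estimated correlation. Adjusted over the list alone, 0 of them passed, with the collagen chains Col4a1 at -1.13 and Col1a2 at -0.72 and the proteoglycan Dcn at -0.62. The 10 choroid plexus and ependymal genes had a median of -0.51 (camera adjusted p = 0.0477), with adjusted p = 0.473 with an estimated correlation, and 4 were lower adjusted over the list alone. Otx2, a transcription factor of choroid plexus, was at -1.50, Ccdc153, an ependymal gene, at -1.44 and Rarres2, chemerin, at -1.02. The choroid plexus list passed in 2 of the 7 fits with a library left out, those without chow replicate 2 or HFD replicate 1, and without chow replicate 3 its median was -0.28. No gene of these 6 lists passed over all genes. Markers of other hypothalamic neurons had a median of -0.01 over 23 genes (adjusted p = 0.518), from -0.09 without chow replicate 3 to 0.21 without HFD replicate 4. Camera did not call the anterior pituitary markers (5 genes, -0.32, and -0.21 without chow replicate 1) or the erythroid markers. The latter were 3 genes at a median of -0.62, with the opposite sign without chow replicate 3 (0.12) and -0.96 without HFD replicate 4. Chow replicate 3 had the oligodendrocyte list at 1.22 and the microglia list at 0.95 above the mean of the P21 libraries.

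**Figure D3:**
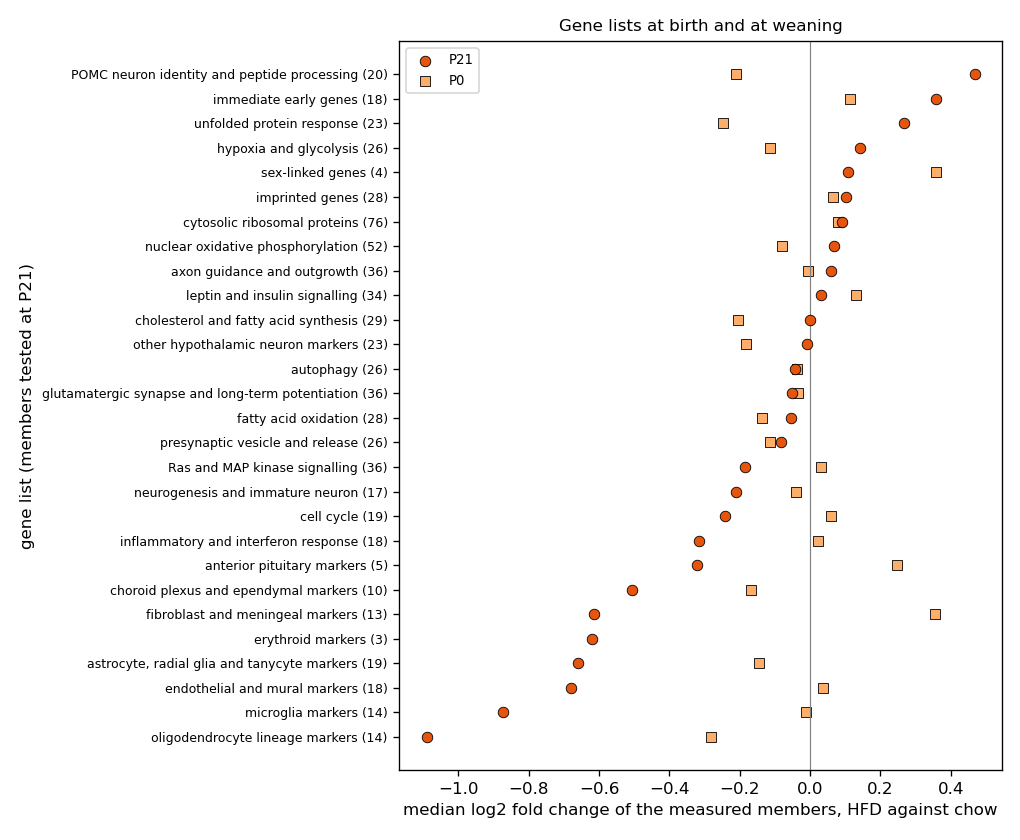
Median log2 fold change of the tested members of each gene list, HFD against chow, at P21 (circles) and P0 (squares), with the number of members tested at P21 in brackets. Oligodendrocyte markers were at -1.09 and microglia markers at -0.87 at P21, and POMC-neuron identity genes at 0.47.

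The P21 test called 25 genes with limma, 14 higher and 11 lower, and 2393 had an unadjusted p under 0.05. In all 25 the groups did not overlap, as in 2268 of all 14070 tested genes (16.1%), where chance gives 5.71%. Camera called 10 of 28 lists, 4 higher and 6 lower, none of which held with an estimated correlation or with fry. With all groups in 1 fit 3 genes rose and 18 fell, 9 of them among the 25, and Cartpt (1.91), Asb4 (1.73) and Npy1r (1.41) did not pass. Asb4, Cartpt and Npy1r were the 3 genes called with every 1 library left out, and the counts were 51 genes without chow replicate 1 (14 higher, 37 lower), 16 without HFD replicate 3 (10 higher, 6 lower) and 19 without chow replicate 3, which stood apart (16 higher, 3 lower), while every fall was lost without chow replicate 2 (6 genes, all higher), HFD replicate 1 (3, all higher) or HFD replicate 4 (7, all higher).

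The comparison of P21 with P0 in chow offspring asks how the pulled-down RNA, which also held markers of other cells, differed between birth and weaning. Pomc rose from 645 ± 481 (mean ± SD, n = 5) to 6875 ± 4516 (n = 3), a log2 change of 3.65 (SE 0.62, adjusted p = 0.000613), and Cartpt from 31.9 ± 41.6 to 630 ± 223 (4.90, SE 0.63). Agrp rose from 13.8 ± 7.96 to 110 ± 87.0 (2.50, SE 0.71, adjusted p = 0.0149), while Npy at 1.24 and Lepr at 0.46 did not pass (adjusted p = 0.103 and 0.395). The call for Agrp was lost without P21 replicate 1 (1.81) and without P21 replicate 2 (2.05). Without P21 replicate 3, which held Npy at 51.9, Npy passed at 2.29 and Agrp was at 3.63, without P21 replicate 1 Npy was at 0.66 and Lepr at 0.19, without P21 replicate 2 Npy was at 0.77, and without P0 replicate 4 Lepr was at 0.23. On the 4 libraries with recovered reads Agrp was at -0.09 with edgeR, the P21 library there being chow replicate 3.

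Apart from Cartpt, the largest rises among the genes named here were in genes of myelin and oligodendrocytes. Mobp, a myelin protein, rose from 7.85 ± 15.3 to 681 ± 283 (7.64) and Mbp from 114 ± 103 to 4840 ± 1523 (5.71). Mog rose by 6.45, Mal by 5.95, Opalin by 5.49, Fa2h by 5.19 and Mag by 4.95. Chow P0 replicate 3 stood apart in these genes, with Mbp at 292 against 42.2 to 105 in the other P0 chow libraries. Of 14 oligodendrocyte genes 11 rose, also 11 adjusted over the list alone, with a median of 3.91, and Cnp, a myelin enzyme, was among them at 3.28. Of 14 microglia genes 10 rose, 12 adjusted over the list alone, among them P2ry12, a purine receptor, by 2.20, Ctss, a lysosomal protease, by 1.95 and Csf1r by 1.56. Both lists were called by camera (adjusted p = 2.6e-07 and 6.83e-05), with adjusted p = 0.244 and adjusted p = 0.399 with an estimated correlation.

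Genes of immature neurons and axon guidance were among those that fell, while the markers of oligodendrocytes (median 3.91) and microglia (1.03) were higher in the same libraries. Dcx, a microtubule protein of migrating neurons, fell from 419 ± 56.7 to 9.55 ± 3.98 (-5.37, SE 0.22) and Sox11, a transcription factor of immature neurons, from 283 ± 97.7 to 13.7 ± 3.94 (-4.24). Cxadr, an adhesion protein, fell by 5.81, St8sia2, a polysialic acid synthase, fell by 5.14, Fat4, an atypical cadherin, fell by 5.14, Trim67 fell by 4.87 and Gpc2, a glypican of developing axons, fell by 4.81. B3gnt5 fell by 4.41, Mex3a, an RNA-binding protein, fell by 4.29 and Fabp7, a lipid carrier of radial glia, fell by 4.20. Of 18 neurogenesis genes 13 fell, 14 adjusted over the list alone, among them Sox4 at -3.32 (camera adjusted p = 8.64e-09, and adjusted p = 0.0179 with an estimated correlation). Of 36 axon guidance genes 24 fell and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 1.45e-06, and adjusted p = 0.0284 with an estimated correlation). Ephb2, an ephrin receptor, fell by 2.27, Robo2, a Slit receptor, fell by 1.77 and Plxna1, a semaphorin receptor, fell by 1.64.

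Proliferation, ribosomal and energy genes also changed with age, beside the higher oligodendrocyte (median 3.91) and microglia (1.03) markers and lower fibroblast markers (-1.43). Of 25 cell cycle genes 21 fell, 22 adjusted over the list alone, among them Rrm2, a ribonucleotide reductase subunit, at -2.88, Ccna2, a cyclin, at -2.24 and Top2a, a topoisomerase, at -2.12. Of 76 ribosomal protein genes 44 fell, 47 adjusted over the list alone, with Rpl15 at -0.90, Rpl29 at -1.17 and Rpl35 at -1.20. Of 26 hypoxia and glycolysis genes 15 rose and 1 fell, and 18 rose and 1 fell adjusted over the list alone. Eno2, the neuronal enolase, rose by 2.52, Aldoa, an aldolase, by 1.88 and Tpi1, triosephosphate isomerase, by 1.37. Of 52 oxidative phosphorylation genes 20 rose, 21 adjusted over the list alone, with Sdha, a succinate dehydrogenase subunit, at 1.51, Ndufs7 at 0.86 and Ndufb5 at 0.85. With an estimated correlation these 4 camera calls had adjusted p = 0.241, adjusted p = 0.495, adjusted p = 0.241 and adjusted p = 0.399, in the order given. Of 20 POMC-neuron identity genes 13 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.000271, and adjusted p = 0.241 with an estimated correlation).

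The age test called 5251 genes with limma out of 14549, 2669 higher and 2582 lower at P21, and 258 of them were unnamed gene models. In 4698 of them the groups did not overlap, as in 5407 of all tested genes (37.2%), where chance gives 3.57%. Camera called 15 of 28 lists, 10 higher and 5 lower, and 2 of them, neurogenesis and axon guidance, held with an estimated correlation. With fry 17 lists were called, 14 of them among those 15. On the 4 libraries with recovered reads edgeR called 886 genes and limma 1172.

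The interaction asks whether the diet difference itself changed between P0 and P21. It was called for 4 of 15037 genes. Heatr8 went from 7.54 ± 1.43 in chow to 3.22 ± 1.099 in HFD offspring at P0 and from 40.3 ± 1.46 to 91.8 ± 6.62 at P21 (difference of log2 changes 2.21, SE 0.32, adjusted p = 0.00618). Tmtc4 went from 41.1 ± 10.01 to 29.3 ± 12.2 at P0 and from 26.8 ± 8.21 to 82.7 ± 14.3 at P21 (2.14, adjusted p = 0.0314). Col11a2 went from 0.224 ± 0.206 to 3.31 ± 1.52 at P0 and from 8.41 ± 2.76 to 3.36 ± 0.505 at P21 (-2.84, adjusted p = 0.00618). Hepacam went from 58.3 ± 9.59 to 78.9 ± 13.6 at P0 and from 104 ± 29.8 to 39.0 ± 5.95 at P21 (-1.79, adjusted p = 0.0106). Groups held 5 and 5 libraries at P0 and 3 and 4 at P21.

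Pomc (1.66, adjusted p = 0.403), Cartpt (2.44, adjusted p = 0.136), Agrp (1.77, adjusted p = 0.348), Npy (1.46, adjusted p = 0.318) and Lepr (0.62, adjusted p = 0.558) did not pass. Without chow P21 replicate 3 Agrp was at 0.64 and Npy at 0.41. Camera called 9 of 28 lists for the interaction. POMC identity (median 0.54), the unfolded protein response (0.42), hypoxia and glycolysis (0.27) and oxidative phosphorylation (0.17) had positive differences, and endothelial (-0.86), microglia (-0.85), oligodendrocyte (-0.78), fibroblast (-0.76) and astrocyte (-0.50) genes had negative ones. With an estimated correlation adjusted p = 0.654 was the lowest, and fry called 0 lists. In the 17 fits with a library left out the POMC identity, unfolded protein, endothelial and microglia lists passed in all 17, the oligodendrocyte and oxidative phosphorylation lists in 16, the astrocyte and fibroblast lists in 14 and the hypoxia list in 9. Oxidative phosphorylation was lost without HFD P21 replicate 3 (0.06) and oligodendrocyte genes without chow P21 replicate 3 (-0.47). Astrocyte genes were lost without HFD P21 replicate 4 (-0.31), chow P0 replicate 4 or chow P21 replicate 3, and fibroblast genes without chow P0 replicate 4 (-0.51), chow P21 replicate 1 or HFD P21 replicate 3. Hypoxia and glycolysis was lost without chow P0 replicates 3, 4 or 5, HFD P0 replicates 1, 2 or 3, chow P21 replicate 1 or HFD P21 replicate 3 (adjusted p up to 0.164), and its median was 0.43 without HFD P0 replicate 5. Of the 14 genes that rose at P21, 13 were below 0 at P0 (median -0.53), 4 of the 14 with an unadjusted p under 0.05 there. Of the 40 genes that fell at P0, 29 were above 0 at P21 (median 0.17), 0 of the 40 with an unadjusted p under 0.05 there. Those 40 moved together between P21 libraries, from a median of -1.48 in HFD replicate 1 to 0.80 in HFD replicate 4 relative to their group. Their direction at P21 therefore depends on the libraries held.

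The interaction had 2290 genes at an unadjusted p under 0.05. Leaving out 1 library gave 2 genes without chow P21 replicate 2, 14 without HFD P21 replicate 2, 36 without HFD P21 replicate 1, 47 without chow P21 replicate 1 and 557 without HFD P0 replicate 5, and Col11a2 and Heatr8 were called in every such fit.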

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

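The tests for a library difference at P0 and for a smaller share of other cells at P21, the GC and Pomc settings, and the splits of the list tests for age and the interaction were chosen only after the data were seen.

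The 40 genes lower in HFD offspring at P0 had a median log2 change of -1.63 and a median GC content of 58.1%, against 49.8% for all tested genes. Removing each library's GC trend left 0.955 of that change (-1.55, 37 of 40 still called), and log2 Pomc in the model left 1.09 of it (-1.77, all 40 still called), which argues against a GC trend or a lower yield of POMC-neuron RNA as the whole cause. Across the 7 P21 libraries, after removal of the diet means, the 40 genes varied together with a median pairwise correlation of 0.909, against at most 0.0996 in 1000 random lists, and 184 of the 200 other genes that followed them most closely at P21 were below 0 at P0 (median -0.82). A factor shared within libraries, such as a difference between library batches, which the labels do not give, may account for the P0 falls. The correlation does not show what that factor is, and random lists cannot tell it from genes that are regulated together. An effect of the dam's diet stays open as untested, since at P0 a batch that coincides with diet and diet itself cannot be told apart. Chance could not be excluded for the number of 41 genes, as 6 of 100 splits drawn from 126 called as many. Such splits count genes and cannot decide on any single gene. The highest other split called 1182 genes (chow replicates 1 and 2 with HFD replicates 1, 2 and 4 against the rest), which points to a structure of the samples other than diet. The libraries named there held Pomc at 90.7 to 246. The rest held it at 657 to 1308, apart from HFD replicate 3 at 102, so that split largely followed Pomc.

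The 14 genes higher in HFD offspring at P21 had a median log2 change of 1.47, and Pomc was at 0.49. They should not exceed Pomc if a smaller share of RNA from other cells in the HFD libraries were the cause. That limit holds only if Pomc came from POMC neurons alone and did not itself change with diet, which was not tested. The anterior pituitary also makes Pomc. Of its genes, Pitx1 was highest at P21 in chow replicate 3 (9.51), but Cga in HFD replicate 4 (44.3). The 14 genes exceeded Pomc by a median of 0.98 (interquartile range 0.40), but by only 0.25 without chow replicate 3, with Pomc then at 0.99. All 14 lay above Pomc in both fits, a count that their choice as called rises favours. The bound used here requires every left-out fit to exceed that range and was made stricter after its result was seen, an earlier bound on all libraries having argued against the explanation. For these libraries alone, the markers of other neurons below argue against an equally smaller share of all other cells only if they came from untagged cells, which was not tested. A smaller share of other cells and an effect of the dam's diet cannot be told apart for these genes while 1 library moves Pomc this far. Of the 35 splits only the real one called as many as the 25 genes at P21, which is the smallest share that so few splits allow. Another split called 22 (chow replicates 2 and 3 with HFD replicate 1 against the rest), so chance was excluded only narrowly.

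The 88 glial, vascular, meningeal and ventricular markers had a median log2 change of -0.80 at P21 (95% bootstrap interval over the genes -0.88 to -0.60), with Mbp at 4840 in chow and 1924 in HFD offspring. A set of 19 markers of other hypothalamic neurons was at -0.16 (-0.37 to 0.46), from -0.28 to 0.19 with a library left out. The lower bound of their interval lay 0.428 above the median of the 88 markers. That bound also lay above this median in each of the 7 fits with a library left out. It did so closely without chow replicate 3 (-0.56 against -0.67) and HFD replicate 2 (-0.58 against -0.83). These intervals resample genes and not libraries, so they leave out the spread between libraries. Members of a list also varied together, with an estimated correlation of 0.66 for the oligodendrocyte list and 0.23 for the list of other hypothalamic neurons. For these libraries alone, and only if the 19 markers came from untagged cells, the values argue against an equally smaller share of all other cells in the HFD libraries. The HA pull-down would also be meant to remove RNA of other cells. Because the tag is also made where the driver gene has been active before, some of the 19 may come from tagged cells, which was not tested. Less RNA from glia and vessels alone, as dissection could give, and an effect of the dam's diet on those cells stay open and were not tested. Chance could not be excluded for the 10 lists called at P21, since 4 of 35 splits called as many (highest other 13). The other splits called a median of 7 lists.

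For age, 1 of 56 splits called as many as the 5251 genes (highest other 2), so chance was excluded. For the interaction, 4 of 100 splits drawn from 8820, the real one included, called as many as 4 genes (highest other 5), so chance was excluded only narrowly, and only for the splits drawn. For the number of gene lists called chance could not be excluded, with 6 of 56 splits calling as many as 15 lists for age (highest other 16). For the interaction 21 of 100 called as many as 9 lists (highest other 12, median of the others 6). These splits count lists and cannot decide on any single list. For age the other splits also divided the P0 and P21 libraries unevenly, and they called a median of 7 lists.

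The diet difference itself differed between ages for 4 genes in the interaction test, Col11a2 (-2.84), Tmtc4 (2.14), Hepacam (-1.79) and Heatr8 (2.21).

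A single library lay far from the rest of its group in 21 of 151 gene and group pairs tested (13.9%), where chance gives about 1 in 20. In HFD P0 replicate 5, Pomc was at 1057 (others 90.7 to 246), Agrp at 25.6 (4.11 to 8.31), Npy at 179 (62.9 to 81.1) and Zc3h3 at 19.6 (31.1 to 34.5). In chow P0 replicate 3, Cartpt was at 106 (7.21 to 22.1) and Vamp1 at 44.8 (19.9 to 25.6). In the same library the myelin genes were also high, with Mobp at 35.2 (0.20 to 3.11), Mog at 14.4 (0.70 to 2.11), Mal at 27.2 (1.68 to 6.29), Mbp at 292 (42.2 to 105), Opalin at 3.52 (0.03 to 0.80) and Mag at 28.6 (9.61 to 12.4). In chow P0 replicate 2, Srrm1 was at 241 (107 to 142), Dcx at 517 (380 to 413) and Fat4 at 953 (304 to 412). In chow P0 replicate 1, Trim67 was at 139 (163 to 165) and Csf1r at 13.5 (20.8 to 22.6). In HFD P0 replicate 3, Ano8 was at 4.35 (0.68 to 1.52). In HFD P21 replicate 2, Lepr was at 12.8 (7.97 to 8.66) and Lhfp at 23.4 (14.0 to 15.0), and in HFD P21 replicate 3, Gjb6 was at 77.0 (46.0 to 47.5).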

How the results depend on the processing

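The robust prior, sample weights, filter at 5, GC trend, log2 Pomc and recovered-read settings, and the list tests for age and the interaction, were chosen after the data were seen. At P0 the main count of 41 became 104 with the replicate block, 355 with 1 surrogate variable, 10 with all groups in 1 fit, 275 with sample weights, 268 with log2 Pomc as a covariate, 3 with edgeR on recovered reads and 24 with limma on the same 5 libraries, and 18 to 135 with a library left out. The P0 count of 0 lists became 3 with the replicate block and 0 to 5 with a library left out. Same-numbered replicates correlated at -0.18 to 0.51 at P0, over 0.1 in 3 of 5 pairs, and at -0.049 to 0.11 at P21, and not every library was closest to its own number. Pairing was taken to need over 0.1 in every pair, so the samples were treated as unpaired, which does not exclude pairing in part. At P21 the count of 25 became 16 with no filter, 3 with the replicate block, 156 with 1 surrogate variable, 42 with the robust prior, 313 with sample weights, 38 with the GC trend removed and 184 with log2 Pomc, and 3 to 51 with a library left out, with no falls called without chow replicate 2, HFD replicate 1 or HFD replicate 4. The 10 lists at P21 became 0 with an estimated correlation and 0 with fry. The ribosomal list at P21 ran from -0.018 without HFD replicate 3, a change of sign, to 0.20 without HFD replicate 4. For age, edgeR on recovered reads gave 886 genes and limma on the same 4 libraries 1172, with Agrp at -0.095 by edgeR, and 2 lists held with an estimated correlation. For the interaction the count of 4 became 10 with upper-quartile rescaling, 65 with the replicate block, 17 with 1 surrogate variable and 1291 with sample weights, and 2 to 557 with a library left out, while its 9 lists became 0 with an estimated correlation and 0 with fry. The recovered-read fits use fewer samples, and for the other settings the cause was not tested. With all libraries kept, the share of called genes that rose, 56% at P21, ran from 14.3% with all groups in 1 fit (3 up, 18 down, 9 shared with the 25) to 66.7% with the replicate block, with 38.0% for sample weights, 41.0% for 1 surrogate variable and 44.1% for upper-quartile rescaling. At P0 it ran from 2.27% to 33.1% (sample weights) around 2.44%, and upper-quartile rescaling moved it from 50% to 20% for the interaction. No rescaling moved the median of all genes by more than 0.06 in size. The other settings gave a count within 1.5 times the main one in 8 cases at P0, 6 at P21, 12 for age and 7 for the interaction. Among single named genes, settings other than leaving out a library kept direction and side of the threshold in 372 cases at P0, 635 at P21, 564 for age and 98 for the interaction, ended a call in 21, 42, 20 and 0, and gave a call in 40, 50, 1 and 1. DESeq2, voom and the Xist covariate were not run. Depth sets the floor of 3 reads, 0.0826 to 0.138 units, and at P21 the simulated 2-fold changes were recovered in 13.4% of genes.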

Other observations

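The gene list tests for age and the values per library given here were chosen after the data were seen.

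Further gene groups differed between P21 and P0 in chow offspring, beside the higher oligodendrocyte (median 3.91) and microglia (1.03) markers in the same libraries. Of 23 markers of other hypothalamic neurons 12 rose and 2 fell with age (median 0.93, camera adjusted p = 0.000243, and adjusted p = 0.241 with an estimated correlation). Of 26 presynaptic genes 13 rose and 3 fell (median 0.68, 0.00801, and adjusted p = 0.399 with an estimated correlation). Of 23 unfolded protein response genes 10 rose and 1 fell (median 0.57, 0.00136, and adjusted p = 0.254 with an estimated correlation), and of 26 autophagy genes 11 rose and 2 fell (median 0.48, 0.00601, and adjusted p = 0.399 with an estimated correlation). Of 18 inflammatory and interferon genes 6 rose (median 0.44, 0.0393, and adjusted p = 0.241 with an estimated correlation), a list that passed in 5 of 8 fits with a library left out and was lost without chow P0 replicate 2, chow P0 replicate 5 or chow P21 replicate 1 (adjusted p up to 0.0805). Of 13 fibroblast and meningeal genes 8 fell (median -1.43, 0.00529, and adjusted p = 0.495 with an estimated correlation). Adjusted over the list alone, the counts were the same for the neuron, presynaptic, inflammatory and fibroblast lists, and 12 rose in each of the unfolded protein response and autophagy lists.

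The amount of Cartpt relative to Pomc varied between libraries. At P21 it was 17.8, 17.1 and 3.24 per 100 units of Pomc in chow replicates 1 to 3, and 28.1, 25.9, 30.7 and 22.4 in HFD replicates 1 to 4. At P0 it ranged from 0.680 to 16.1 in chow and from 0.75 to 17.02 in HFD libraries. Pitx1, a transcription factor of the anterior pituitary, where Pomc is also made, was at 9.51 in chow P21 replicate 3 and at 0.14 to 2.54 in the other P21 libraries. Cga, a second gene of the anterior pituitary, was highest in HFD P21 replicate 4 at 44.3, with 24.3 in chow P21 replicate 3 and 8.40 to 19.1 in the other P21 libraries. Ttr, the main transcript of choroid plexus, ranged from 8.03 to 1126 between P0 libraries and from 12.1 to 33.5 between P21 libraries.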
